A study of Mus musculus with 6 samples.

How the data were processed

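Nuclei of the left ventricle of 6 mice were profiled by single-nucleus RNA sequencing, 1 library per mouse, in 3 groups of 2 mice. Wild-type mice (WT) and mice labelled as knockouts of the gene for lamin A and C (Lmna-KO) had received phosphate-buffered saline, and a further group of Lmna-KO mice (Lmna-KO+AAV) had received an adeno-associated virus carrying Lmna, injected into the chest on postnatal day 2. Groups and replicate numbers were taken from the sample labels, which place all 6 libraries in the same batch and give neither the sex nor the age of the mice. Per the labels' protocols, nuclei came from snap-frozen tissue in an automated isolation system, and libraries were made with droplet chemistry that reads the 3′ end of each RNA. Each pair is described as separate mice, so the spread between libraries includes both biological and technical variation.

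The deposited values are raw counts of unique molecular identifiers (UMIs) per gene and barcode in filtered matrices, per the labels. Cell Ranger 7.1.0 and Seurat are named in the submitters' processing notes together with the mouse build GRCm38 (mm10); which tool made which step, and how barcodes were separated from empty droplets, is not given in the sources used here. The lowest barcode in the matrices held 500 UMIs. Whether counting used strand, and whether the vector sequence was part of the reference, is likewise not given. Of the 32285 genes in the matrices, 32235 (99.8%) were matched to the GRCm38 annotation for chromosome and position.

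Barcodes with at least 500 UMIs, at least 300 genes and under 5% mitochondrial UMIs were kept, which left 52821 of 59070. Doublet scores were computed per library with the Scrublet method in scanpy 1.11.5. Its automatic threshold marked between 0 and 1486 nuclei per library, so the nuclei with the highest scores were removed at a fixed rate of 0.8% per 1000 barcodes, which left 48142. Counts were log-normalised, 2000 variable genes (without Lmna and the sex-linked genes used as checks) were reduced to 30 principal components, and a graph of 20 neighbours was clustered by the Leiden algorithm (leidenalg 0.10.2) at resolution 1.0. Each of the resulting clusters was named from marker genes fixed before the data were examined. The scoring thresholds, and the reasons for leaving a cluster unnamed (a second type scoring nearly as high, a median doublet score above 0.1, or leading genes of the cell cycle or of neurons), were set after the clusters had been seen. The unnamed nuclei made up 12.2% and 2.41% of the 2 WT libraries, 5.98% and 5.26% of the Lmna-KO libraries and 5.38% and 3.40% of the Lmna-KO+AAV libraries.

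Counts were summed per library over the nuclei of a class, because nuclei are not replicates, for each class with at least 50 nuclei in every library that the design named: cardiomyocytes, fibroblasts, endothelial cells and macrophages. The sums were tested with edgeR 4.0.16 (R 4.3.3), using TMM factors, filterByExpr and the robust quasi-likelihood test on a fit of all 6 libraries, which leaves 3 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over the genes tested in the class, and a gene was called at an adjusted p under 0.05 with no threshold on the fold change. Fold changes are log2 values with standard errors (SE) from that fit, and levels are given as CPM, scaled by the summed UMIs of the class in the library. An exact permutation test of 2 libraries against 2 cannot pass that threshold and was not used.

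A total of 25 gene lists were fixed before the data were examined, each for the classes it fits, and tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a class and comparison. Camera with an estimated correlation, and fry, which asks whether the genes of a list move on balance one way, were run beside it. No list kept its call with the estimated correlation in any class or comparison. A list needed at least 5 measured members. The cell cycle list had fewer outside cardiomyocytes and was tested in cardiomyocytes only. A cluster of 176 nuclei led by cell cycle genes, which scored highest for macrophages, had been left unnamed and so entered none of the tested classes.

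Genes named in the text were chosen by a rule also fixed beforehand: per class and comparison, among called genes with a mean of at least 10 CPM (20 outside cardiomyocytes) and no overlap between the groups' libraries, the 10 (5 outside cardiomyocytes) with the largest rise and the 10 (5) with the largest fall. Predicted gene models, mitochondrial and ribosomal protein genes were left out, and outside cardiomyocytes also genes over 4 times higher in cardiomyocytes. Lmna in each class, up to 4 members of each list with the smallest p, and Xist, Ddx3y, Uty, Kdm5d and Eif2s3y as a check of the mice completed the rule. The groups compared, the tests, the alternatives and these rules were all set before the data were examined, except where a later choice is stated.

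Nuclei per class were tested with edgeR on the numbers of nuclei, with exact Clopper-Pearson intervals for each share at 95% confidence. Shares of nuclei with a Lmna UMI were taken after thinning each nucleus to 1000 UMIs. These intervals, and the upper limits given by 3 counts where a share was 0, cover counting error only. The edgeR step was tested on simulated counts with the means and library sizes of the real genes. For Lmna-KO against WT in cardiomyocytes, among 16488 genes, it recovered 6% of 2-fold, 60% of 4-fold, 78% of 8-fold and 88% of 16-fold changes, with 12 false calls among 128. Recovery of 4-fold changes was 72% in fibroblasts, 70% in endothelial cells and 56% in macrophages. Between libraries the estimated coefficient of variation was 26.9% in cardiomyocytes, 21.5% in fibroblasts, 20.5% in endothelial cells and 26.3% in macrophages. The replicate libraries of each group differed by more than counting noise (chi-square per degree of freedom 59.2, 39.1 and 60.3), which does not show that they came from separate mice.

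The alternatives were DESeq2 1.42.0, other size factors, no filter on low counts, a fit of only the 4 libraries compared, the replicate number as a block, no doublet removal, a stricter filter on nuclei (at least 1000 UMIs, 500 genes and under 1% mitochondrial UMIs), another clustering resolution, thinned sums, and leaving out each library in turn. Settings added after seeing the data were a fit without genes on chromosomes X and Y, cardiomyocytes without clusters 14 and 17, and a split of the Lmna-KO libraries between the comparisons that share them.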

Results

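Left ventricular nuclei were collected from 2 WT, 2 Lmna-KO and 2 Lmna-KO+AAV mice. The WT libraries held 7963 and 14682 barcodes with 39232270 and 41228233 UMIs, the Lmna-KO libraries 5866 and 5393 barcodes with 19923432 and 17013992, and the Lmna-KO+AAV libraries 11902 and 13264 barcodes with 41070017 and 32740850. Median depth per barcode was 3666 and 2119 UMIs in WT, 2520 and 2167 in Lmna-KO, and 2616 and 1681 in Lmna-KO+AAV. In Lmna-KO+AAV replicate 2 the filter on mitochondrial UMIs removed 4413 barcodes, against 64 to 660 in the other libraries, and its median mitochondrial share was 3.67%. After filtering, 48142 nuclei remained, and cardiomyocytes were the largest named class, with 2185 and 3909 nuclei in WT, 2770 and 1993 in Lmna-KO and 5856 and 3776 in Lmna-KO+AAV. Cardiomyocytes of different libraries lay largely in different clusters. Cluster 0 held 89.8% and 91.6% of WT cardiomyocytes, cluster 7 held 88.4% of those of Lmna-KO replicate 1, and clusters 1 and 13 held 36.8% and 24.99% of those of Lmna-KO replicate 2. Cluster 1 held 81.8% of cardiomyocytes of Lmna-KO+AAV replicate 1 and cluster 3 held 82.3% of those of replicate 2. Across cardiomyocyte genes the root mean square log2 difference was 0.42 between the WT replicates, 0.51 between the Lmna-KO replicates and 0.48 between the Lmna-KO+AAV replicates, while Lmna-KO replicate 2 and Lmna-KO+AAV replicate 1 differed by 0.38.

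The targeted gene, Lmna (chromosome 3, 88480147 to 88509956, minus strand, GRCm38), encodes lamins A and C of the nuclear lamina. In cardiomyocytes its level was 38.8 and 59.2 CPM in WT, 33.4 and 37.8 CPM in Lmna-KO, and 376 and 790.5 CPM in Lmna-KO+AAV. The difference between Lmna-KO and WT was not called by edgeR (log2 fold change -0.64, SE 0.34, adjusted p = 0.491, n = 2 per group). In simulated counts that test recovered only 6% of 2-fold changes, so a difference of this size is not excluded. Both Lmna-KO libraries lay below both WT libraries here and in endothelial, endocardial and pericyte nuclei, but not in fibroblasts or macrophages. The labels do not give the deleted part of the gene, and a 3′ tag outside it checks nothing, so these values do not test the knockout labels. With the vector, cardiomyocyte Lmna rose by 4.08 (log2, SE 0.38, adjusted p = 0.0149 by edgeR) over Lmna-KO and by 3.44 (SE 0.37, adjusted p = 0.00723) over WT. Over Lmna-KO it was not called with only the 4 libraries compared, without doublet removal or with the stricter nuclei filter. The rise over Lmna-KO lost its call without Lmna-KO replicate 1 (4.02, adjusted p = 0.114), and the rise over WT lost it without WT replicate 1 (3.20, adjusted p = 0.130) or replicate 2 (3.67, adjusted p = 0.0756). Without clusters 14 and 17, a setting chosen after seeing the data, both rises were smaller and not called, at 2.72 (adjusted p = 0.175) and 2.07 (adjusted p = 0.127). Lmna is among the 10 top genes of both clusters, so leaving them out lowers its rise by construction.

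At 1000 UMIs per nucleus, 3.87% (exact 95% interval 3.10 to 4.77) and 6.15% (5.42 to 6.96) of WT cardiomyocytes held a Lmna UMI. The shares were 3.51% (2.84 to 4.28) and 3.58% (2.76 to 4.54) in Lmna-KO, and 16.4% (15.5 to 17.4) and 25.5% (24.1 to 27.0) in Lmna-KO+AAV. Thinning left out 16 and 25 WT, 121 and 203 Lmna-KO, and 78 and 147 Lmna-KO+AAV cardiomyocytes, and unthinned shares averaged 19.7% ± 0.84, 11.4% ± 0.92 and 41.9% ± 5.60 (SD, n = 2). No class in this tissue is known to lack Lmna. For fibroblasts of Lmna-KO+AAV, the thinned shares were 15.4% (13.002 to 17.96) and 16.5% (13.7 to 19.7), at median depths of 2005 and 2202 UMIs against 3558 and 2825 in cardiomyocytes, so that in replicate 1 the intervals of both classes overlapped. Nuclei with 10 or more Lmna UMIs made up 2.36% and 5.56% of Lmna-KO+AAV cardiomyocytes (138 of 5856 and 210 of 3776), and 0 were found in the other 4 libraries.

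Outside cardiomyocytes, Lmna was also higher with the vector, although the series title describes re-expression in cardiomyocytes. Endothelial Lmna was 53.6 and 61.5 CPM in WT, 39.1 and 32.6 in Lmna-KO and 162 and 197 in Lmna-KO+AAV, a rise of 2.42 over Lmna-KO (log2, SE 0.22, edgeR adjusted p = 0.00474, n = 2 per group). That call was lost without Lmna-KO+AAV replicate 1 (2.57, adjusted p = 0.0555) or replicate 2 (2.27, adjusted p = 0.158). Without the 3 and 2 endothelial nuclei of 10 or more Lmna UMIs, the levels with the vector were 143 and 125 CPM. Fibroblast Lmna was 173 and 427 CPM with the vector against 46.7 and 72.6 in Lmna-KO (2.34, SE 0.42, adjusted p = 0.201 by edgeR), and without a single nucleus of 10 or more Lmna UMIs the level in replicate 2 was 186 CPM. Macrophage Lmna was 180 and 212 CPM against 52.96 and 70.7 (1.64, SE 0.33, adjusted p = 0.612). Relative to WT, Lmna with the vector rose by 1.67 in endothelial cells (SE 0.21, adjusted p = 0.00849 by edgeR) and by 1.96 in fibroblasts (SE 0.39, adjusted p = 0.0454), and stood 1.48 higher in macrophages (SE 0.30, adjusted p = 0.175). The endothelial call was lost without WT replicate 1 (1.61, adjusted p = 0.0741) or Lmna-KO+AAV replicate 1 (1.81, 0.0842) or 2 (1.51, 0.140). The fibroblast call was lost without WT replicate 1 (1.82, 0.328) or 2 (2.12, 0.154), Lmna-KO replicate 2 (1.95, 0.0511) or Lmna-KO+AAV replicate 2 (1.18, 0.327). Lmna-KO against WT gave -0.38 in fibroblasts, -0.76 in endothelial cells and -0.16 in macrophages, with adjusted p of 0.805, 0.223 and 0.928.

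**Figure D1:**
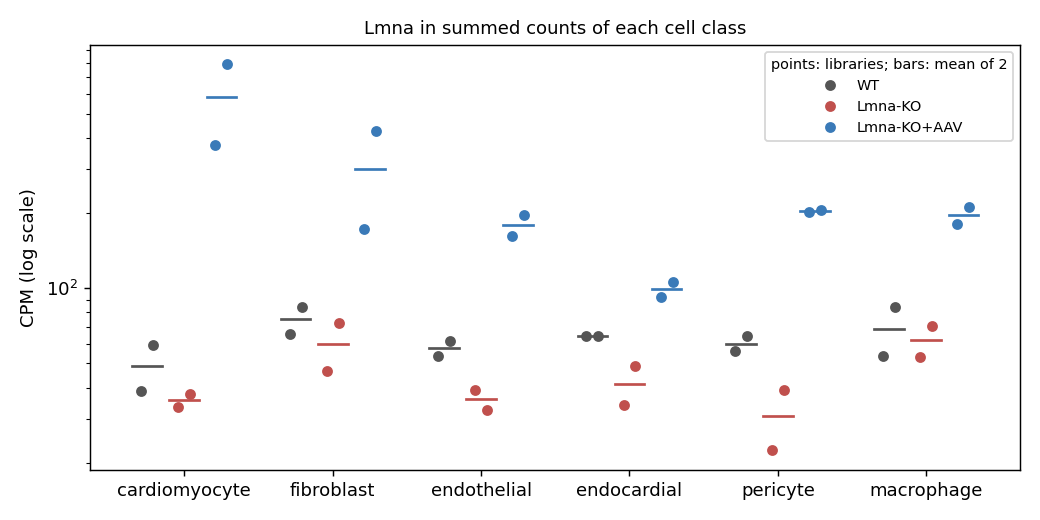
Lmna level in CPM of summed counts (log axis) in 6 classes of nuclei, with a point for each library and a bar for the mean of the 2 libraries of each group. Both Lmna-KO+AAV libraries lie above all other libraries in each class shown, with 376 and 790.5 CPM in cardiomyocytes.

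Sex-linked genes separated WT from the other groups. Xist (chromosome X, 103460366 to 103483254), the RNA that silences 1 X chromosome in females, was at 1124 and 998 CPM in WT cardiomyocytes and between 8.20 and 9.10 CPM in the other 4 libraries. The Y-linked gene Uty was at 0.139 and 0.0641 CPM in WT, 278 and 277 in Lmna-KO and 266 and 245 in Lmna-KO+AAV, while Ddx3y, Kdm5d and Eif2s3y, also on chromosome Y, had 0 counts in WT. The WT mice thus read as female and the mice of both other groups as male. Every comparison with WT below is therefore also a comparison of sexes, and the 2 cannot be told apart, whereas Lmna-KO+AAV and Lmna-KO are both male.

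The first comparison asked how cardiomyocytes of Lmna-KO differed from WT. Fatty acid oxidation genes fell in Lmna-KO relative to WT: 23 of 26 measured members were lower, with a median log2 change of -0.51 (camera adjusted p = 0.00478; adjusted p = 0.847 with an estimated correlation). Among them, Ppara, the receptor that switches on fatty acid use, was at 416 and 364 CPM against 563 and 600 in WT (-0.76, SE 0.26, adjusted p = 0.291 by edgeR), and Cpt1b, which brings fatty acids into mitochondria, at 194 and 105 CPM against 226 and 269 (-0.90, SE 0.33, adjusted p = 0.328). Lists for calcium handling, ion channels, the dystrophin complex and costamere, and the sarcomere also fell. Calcium handling had 10 of 13 members lower (median -0.39, camera adjusted p = 0.0213), including the calcium release channel gene Ryr2 (-0.97, SE 0.31) and Cacna2d1 (-0.75, SE 0.24). Ion channel genes were lower in 9 of 14 (median -0.58, adjusted p = 0.0291), among them the potassium channel gene Kcnh2 (-0.75, SE 0.24). The dystrophin and costamere list was lower in 12 of 15 (median -0.29, adjusted p = 0.0252), with Plec at -1.20 (SE 0.28) and Dmd at -0.58 (SE 0.28). Sarcomere genes were lower in 15 of 20 (median -0.25, adjusted p = 0.0484), but not in common: Ttn, at 21878 and 18085 CPM against 60421 and 31751, gave -1.42 (SE 0.38), whereas Myl3 gave 0.99 (SE 0.24) and Myom2 1.36 (SE 0.42). Targets of p53 rose, with 17 of 20 higher (median 0.46, camera adjusted p = 0.0213), among them Rps27l (1.41, SE 0.36) and Eda2r (1.63, SE 0.49). With an estimated correlation these 5 lists gave adjusted p = 0.839 for calcium handling and adjusted p = 0.815 for the others. Adjusted over the list alone, 3 sarcomere genes (1 higher, 2 lower) and 1 costamere gene passed, and 0 in the other 4 lists. The lists were not tested without their members on chromosomes X and Y.

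The remaining 12 lists were not called in this comparison, with camera adjusted p from 0.0789 to 0.974. They were stress and fetal genes, intercalated disc, glycolysis, nuclear-encoded respiratory chain, integrated stress response, nuclear envelope, atrophy and autophagy, glucocorticoid-responsive genes, circadian clock, MAPK response, interferon response and cell cycle. Respiratory chain genes were higher in 17 of 19 (median 0.24). Of the 14 stress and fetal genes, 7 (5 higher, 2 lower) passed when adjusted over the list alone and 0 over all genes. The glucocorticoid list had a median of -0.03 with a mean and test above 0, the integrated stress response list a median of 0.01 with a mean and test below 0, and the intercalated disc and glycolysis lists medians and means above 0 with a test below 0. Gene by gene, edgeR called 6 of 16488 genes between Lmna-KO and WT cardiomyocytes (5 higher, 1 lower), all on chromosome X or Y, and 0 elsewhere. At an unadjusted p under 0.05 there were 2040, where chance gives 824, and DESeq2 called 328. The count was 13 and 24 without Lmna-KO replicate 1 and 2, and 15 and 18 without Lmna-KO+AAV replicate 1 and 2. No member of the called lists passed over all genes. All 6 list calls were lost without WT replicate 1 (adjusted p from 0.119 to 0.185). Without Lmna-KO replicate 2, fatty acid oxidation, p53 targets and sarcomere (0.199), ion channels (0.189) and calcium handling (0.0631) were lost. Without Lmna-KO replicate 1, calcium handling and sarcomere (0.108), ion channels (0.0649) and dystrophin and costamere (0.211) were lost. Without WT replicate 2, ion channels (0.117) and sarcomere (0.0553) were lost, and the sarcomere call also ended without Lmna-KO+AAV replicate 1 (0.0546) or replicate 2 (0.0553), with RLE size factors (0.0531), no doublet removal (0.0652) or Leiden resolution 0.5 (0.0537), and without clusters 14 and 17 (0.0671). The stricter nuclei filter ended the ion channel call (0.142).

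The second comparison asked what the vector changed in the knockout. In cardiomyocytes, edgeR called 10 of 16488 genes between Lmna-KO+AAV and Lmna-KO, all 10 higher with the vector. BC018473 (chromosome 11, 116752167 to 116759373, plus strand, annotated as an antisense RNA), was at 0.477 and 1.68 CPM in Lmna-KO and 1349 and 3006 CPM in Lmna-KO+AAV, a log2 rise of 11.10 (SE 0.69, adjusted p = 0.00145, n = 2 per group). Because the use of strand in counting is not given, its reads cannot be told from those of a gene on the other strand. Kazn (chromosome 4, 142102390 to 142239401), which encodes a desmosome-associated protein, rose from 20.5 and 23.4 to 174 and 370 CPM (3.68, SE 0.37, adjusted p = 0.0175). Dancr (chromosome 5, 74093060 to 74095406), a long non-coding RNA, rose from 34.0 and 38.9 to 135 and 151 CPM (2.02, SE 0.23, adjusted p = 0.0238). The other called genes were Lmna, Stac2, Sfta2, Gm9750, Gm39302, Gm47507 and 4833417C18Rik; all but Lmna lie outside the naming rule and were listed after their values were seen. Without clusters 14 and 17 the calls dropped to 1, and Kazn gave 1.68 (adjusted p = 0.175) and Dancr 0.83 (adjusted p = 0.609). BC018473, Dancr, Kazn, Nppb and Lmna are among the 10 top genes of cluster 17, and Lmna, Nppb and Ankrd1 among those of cluster 14, so this setting lowers their changes by construction. Of cardiomyocytes, cluster 14 held 0.0458% and 0.0256% in WT, 0.758% and 4.72% in Lmna-KO and 6.80% and 7.20% with the vector, and cluster 17 held 0 in WT, 0 and 0.1004% in Lmna-KO and 4.88% and 7.07% with the vector. Without Lmna-KO replicate 1 the count was 3, with Kazn at 3.61 (adjusted p = 0.122) and Dancr at 1.96 (adjusted p = 0.131). Dancr was also lost without WT replicate 1 (2.00, adjusted p = 0.0606) or 2 (2.02, adjusted p = 0.0502), and without Lmna-KO+AAV replicate 2 (1.94, adjusted p = 0.0926). With only the 4 libraries compared, Kazn (0.0806) and Dancr (0.0839) were not called, nor without doublet removal (1.84, adjusted p = 0.124, and 1.14, adjusted p = 0.277), nor Dancr with the stricter nuclei filter (0.0668). The count was 5 without WT replicate 1, 6 without Lmna-KO+AAV replicate 2, 42 without Lmna-KO replicate 2 and 71 without Lmna-KO+AAV replicate 1. Higher counts came with DESeq2, RLE size factors and no filter on low counts. Lower ones came with only the 4 libraries compared, without doublet removal and with the stricter nuclei filter. At an unadjusted p under 0.05 there were 1488 genes, where chance gives 824.

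Of the 18 lists, 8 rose in cardiomyocytes with the vector and 0 fell. The interferon response was among them, with 15 of 16 members higher (median 1.01, camera adjusted p = 6.89e-07; adjusted p = 0.492 with an estimated correlation). Its members were low, with the antiviral regulator Usp18 at 1.52 and 3.74 CPM in Lmna-KO and 10.8 and 7.92 with the vector (1.91, SE 0.52, adjusted p = 0.295 by edgeR), and Ifit1 at 0.858 and 1.55 against 3.50 and 3.76 (1.66, SE 0.49, adjusted p = 0.334). MAPK response genes were higher in 13 of 15 (median 1.04, camera adjusted p = 0.000168), with the growth regulator gene Myc at 2.39 (SE 0.63) and Jun at 1.65 (SE 0.50). The integrated stress response was higher in 13 of 18 (median 0.80, adjusted p = 0.000442), with its transcription factor gene Atf4 at 1.005 (SE 0.23) while Cth, for cysteine synthesis, gave -2.74 (SE 0.49). Stress and fetal genes were higher in 11 of 14 (median 1.19, adjusted p = 0.00227). Among these Nppb, which encodes B-type natriuretic peptide, was at 47.9 and 84.7 CPM in Lmna-KO and 250 and 411 CPM with the vector (2.37, SE 0.34, adjusted p = 0.0538 by edgeR), and Ankrd1 at 411 and 257 against 561 and 1037 (1.29, SE 0.35, adjusted p = 0.293). Cell cycle genes were higher in 12 of 14 (median 0.99, adjusted p = 0.00130), at low levels such as 0.381 and 1.81 CPM of Mki67 against 2.39 and 2.74. Fatty acid oxidation was higher in 22 of 26 (median 0.53, adjusted p = 0.00466), with Slc25a20 at 1.12 (SE 0.27) and Acadvl at 0.89 (SE 0.26). Targets of p53 were higher in 15 of 20 (median 0.35, adjusted p = 0.00982), with Btg2 at 3.30 (SE 0.56) and Plk2 at 1.47 (SE 0.27), and glucocorticoid-responsive genes in 10 of 11 (median 0.53, adjusted p = 0.0157). With an estimated correlation the integrated stress response gave adjusted p = 0.419, the MAPK, stress and fetal, cell cycle and p53 lists adjusted p = 0.492, glucocorticoid-responsive genes adjusted p = 0.565 and fatty acid oxidation adjusted p = 0.588.

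Over all genes, 0 members of these 8 lists were called by edgeR. Adjusted over the list alone, 6 passed in the interferon response, 6 in stress and fetal genes, 6 in the integrated stress response (5 higher, 1 lower), 4 in fatty acid oxidation, 2 each in the MAPK response and p53 targets, and 0 in the cell cycle and glucocorticoid lists. Without Lmna-KO replicate 2, fatty acid oxidation (adjusted p = 0.389) and the glucocorticoid list (0.459) were not called, and without Lmna-KO+AAV replicate 1 the fatty acid oxidation list turned to the lower side (0.891) and p53 targets were lost (0.0714). Without Lmna-KO replicate 1, p53 targets (0.206) and the cell cycle (0.207) were lost, and without Lmna-KO+AAV replicate 2 the glucocorticoid list (0.357). Without clusters 14 and 17 the integrated stress response (0.182) and p53 targets (0.200) were not called, nor p53 targets without doublet removal (0.06996) or the cell cycle with the stricter nuclei filter (0.312). The 10 lists not called were sarcomere, calcium handling, ion channels, intercalated disc, dystrophin and costamere, glycolysis, respiratory chain, nuclear envelope, atrophy and autophagy, and circadian clock, with adjusted p from 0.0622 to 0.901. The atrophy list had a median of 0.05 and a mean of 0.08 with a test below 0, and the nuclear envelope list a mean of 0.04 with a median and test below 0.

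The third comparison asked what still differed from WT after the vector. In cardiomyocytes, 3 stress and fetal genes were higher in Lmna-KO+AAV than in WT: Nppb was at 250 and 411 CPM against 23.5 and 21.8 (log2 change 3.72, SE 0.36, adjusted p = 0.00334 by edgeR, n = 2 per group), Ankrd1 at 561 and 1037 against 133 and 152 (2.35, SE 0.36, adjusted p = 0.0279), and Ccn2, for a matricellular growth factor, at 91.0 and 144 against 17.7 and 14.1 (2.73, SE 0.38, adjusted p = 0.0228). Lower genes included Whrn (-2.63, SE 0.30, adjusted p = 0.00723), Itpr2, an intracellular calcium channel gene (-1.51, SE 0.27, adjusted p = 0.0404), and Myh7b, a myosin heavy chain gene (-1.45, SE 0.27, adjusted p = 0.0440). In all, edgeR called 145 of 16488 genes (125 higher, 20 lower), of which 7 lie on chromosome X or Y. More were called with DESeq2, without a filter on low counts, with only the 4 libraries compared and with the replicate block. Fewer were called with thinned sums and without doublet removal. BC018473 (12.80, SE 0.75, adjusted p = 0.000142), Kazn (4.04, SE 0.38, adjusted p = 0.00296) and Dancr (3.04, SE 0.24, adjusted p = 0.000575) were again among the higher genes. Every mouse with the vector was male and every WT mouse female, so these values carry that difference as well. Without WT replicate 1, 8 genes were called and Kazn (adjusted p = 0.0853), Nppb (0.0786), Ankrd1 (0.195), Ccn2 (0.140), Whrn (0.0670), Itpr2 (0.202) and Myh7b (0.222) were not. Without WT replicate 2, 15 were called, and Nppb (0.0756), Ankrd1 (0.133), Ccn2 (0.130), Itpr2 (0.123) and Myh7b (0.119) were not. Without Lmna-KO+AAV replicate 2, 25 were called, and Ankrd1 (1.83, adjusted p = 0.0884), Ccn2 (2.35, 0.0810), Itpr2 (0.131) and Myh7b (0.179) were not, and without replicate 1 Itpr2 (0.134) and Myh7b (0.135) were not. Without Lmna-KO replicate 1 or 2 the count was 528, and without clusters 14 and 17 it was 19. There Ankrd1 (2.24, adjusted p = 0.0904), Ccn2 (2.34, 0.150), Itpr2 (-1.37, 0.141) and Myh7b (-1.29, 0.148) were not called. Without doublet removal Ccn2 (0.0737), Itpr2 (0.0621) and Myh7b (0.0706) were not, nor Myh7b with thinned sums (0.0533).

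Among the lists, 6 rose and 1 fell in Lmna-KO+AAV cardiomyocytes relative to WT. The MAPK response was higher in 15 of 15 members (median 1.08, camera adjusted p = 8.82e-06; 5 passed adjusted over the list alone and 0 over all genes) and the interferon response in 16 of 16 (median 0.95, adjusted p = 8.82e-06; 3 and 1), with Bst2 at 2.11 (SE 0.39, adjusted p = 0.0469 by edgeR). Targets of p53 were higher in 18 of 20 (median 0.72, adjusted p = 4.33e-05; 9 passed over the list alone and 2 over all genes, Plk2 at 1.95 and Rps27l at 1.96). Stress and fetal genes were higher in 12 of 14 (median 0.84, adjusted p = 0.00302; 5 and 3), and Nppa, for atrial natriuretic peptide, stood at 508 and 334 CPM against 10.0 and 16.3 (4.88, SE 0.88, adjusted p = 0.0614 by edgeR). In Lmna-KO, Nppa was at 73.4 and 502 CPM. Respiratory chain genes were higher in 17 of 19 (median 0.42, adjusted p = 0.00668; 5 and 0), with Cox6a2 at 1.16 (SE 0.24), and the integrated stress response in 14 of 18 (median 0.87, adjusted p = 0.00668; 8, of which 7 were higher, and 1), with Atf4 at 1.33 (SE 0.23). Ion channel genes fell, with 11 of 14 lower (median -0.62, adjusted p = 0.00302; 4 and 0), including Kcnh2 at 53.8 and 43.0 CPM against 72.7 and 103 (-0.99, SE 0.24, adjusted p = 0.0791 by edgeR). With an estimated correlation the MAPK, p53, ion channel and integrated stress response lists gave adjusted p = 0.332, the interferon and stress and fetal lists adjusted p = 0.4003, and the respiratory chain adjusted p = 0.715. The stress and fetal call was lost without Lmna-KO+AAV replicate 2 (0.0645), and the respiratory chain without that library (0.124) or WT replicate 1 (0.121). Plk2, Rps27l, Bst2 and Atf4 were not called without WT replicate 1 (adjusted p = 0.130, 0.234, 0.224 and 0.224), WT replicate 2 (0.119, 0.142, 0.119 and 0.153) or Lmna-KO+AAV replicate 2 (0.0810, 0.188, 0.160 and 0.197), and Rps27l (0.0869) and Bst2 (0.137) were not called without Lmna-KO+AAV replicate 1. Without doublet removal the 4 genes gave 0.0538, 0.0737, 0.0670 and 0.102, with the stricter nuclei filter 0.0543, 0.0719, 0.0740 and 0.0547, and without clusters 14 and 17 0.154, 0.145, 0.130 and 0.199; thinned sums ended the calls of Rps27l (0.0505), Bst2 (0.0668) and Atf4 (0.0522). Without clusters 14 and 17 the integrated stress response gave adjusted p = 0.562, and without doublet removal 0.0705, while the stricter filter gave 0.158 for the respiratory chain. The other 11 lists, fatty acid oxidation with 13 of 26 higher among them, gave adjusted p from 0.0686 to 0.972. The sarcomere, intercalated disc, fatty acid oxidation and circadian clock lists had medians above 0 with tests below 0.

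**Figure D2:**
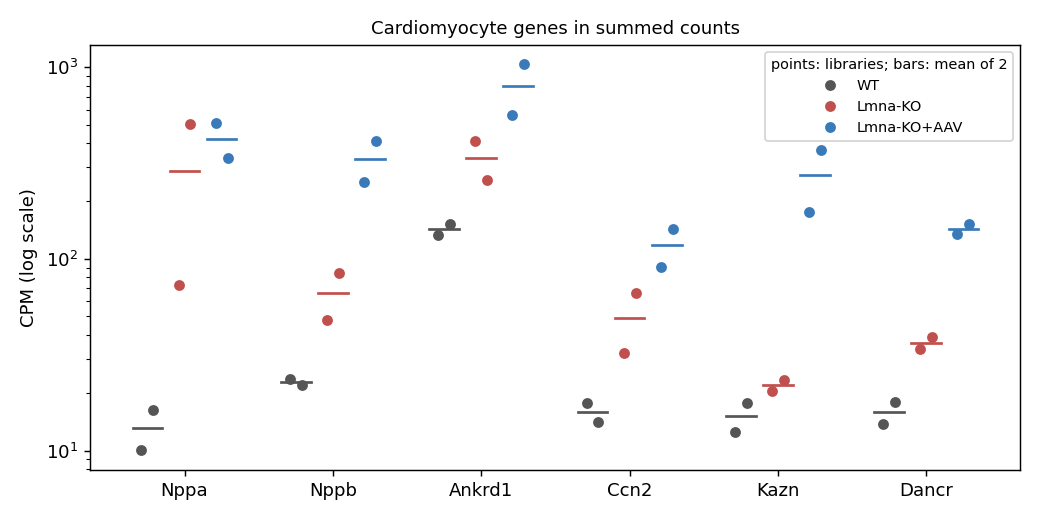
Levels of 6 genes in summed cardiomyocyte counts (CPM, log axis), with a point for each library and a bar for the mean of the 2 libraries of each group. Nppb lies at 23.5 and 21.8 CPM in WT, 47.9 and 84.7 in Lmna-KO and 250 and 411 in Lmna-KO+AAV, and Kazn and Dancr are highest in both Lmna-KO+AAV libraries.

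Whether the vector moved knockout changes back was asked from genes changed in both comparisons in opposite directions. In cardiomyocytes, 0 genes were called by edgeR both in Lmna-KO against WT and, in the opposite direction, in Lmna-KO+AAV against Lmna-KO, and DESeq2 gave 27. At an unadjusted p under 0.05, 330 genes moved in opposite directions, against a median of 173 (159 to 207) in 50 simulated sets with no group effect, and 72 moved in the same direction, against 2 (0 to 4). The observed lists were longer, with 1196 genes higher and 844 lower in Lmna-KO and 959 higher and 529 lower with the vector, against simulated medians of 386.5, 377.5, 392.5 and 377.5, which by itself raises both overlaps. Independent lists would share 38.4 genes higher in Lmna-KO and lower with the vector, where 150 were observed, and 49.1 in the other direction, where 180 were observed. Across genes, which are not independent replicates, the fold changes correlated at r = -0.22, against -0.53 in the simulated sets, with a covariance of -0.114 against -0.129, a difference of 0.0145. Both Lmna-KO libraries enter both comparisons, which by itself yields opposite changes, as in the simulated sets. In a test added after these values were seen, each Lmna-KO library entered 1 comparison only. With replicate 1 against WT and replicate 2 against Lmna-KO+AAV, 129 genes moved in opposite directions and 130 in the same one (r = -0.07, covariance -0.0629), the former 52 higher and 77 lower in Lmna-KO where independent lists would share 24.97 and 34.5. With the libraries exchanged, 141 moved in opposite directions and 376 in the same one (r = 0.13, covariance 0.146), the former 48 higher and 93 lower where independent lists would share 48.5 and 74.3. The sign thus changed with the library used, and the excess of opposite changes over same ones was in neither split. EdgeR called 0 genes in opposite directions in either.

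In fibroblasts, the metallothionein genes Mt1 and Mt2, whose products bind metals, rose in Lmna-KO relative to WT. Mt1 was at 74.9 and 85.7 CPM against 12.4 and 10.1 (log2 change 2.77, SE 0.29, adjusted p = 0.00245 by edgeR, n = 2 per group) and Mt2 at 15.97 and 36.3 against 1.15 and 0.172 (5.32, SE 0.68, adjusted p = 0.0197). The Mt2 call was lost without Lmna-KO replicate 2 (4.57, adjusted p = 0.0583), Lmna-KO+AAV replicate 1 (5.30, 0.0735) or replicate 2 (5.31, 0.0633), and with only the 4 libraries compared (0.129). Glucocorticoid-responsive genes, a list that holds both, rose with 9 of 11 higher (median 0.19, camera adjusted p = 0.0207; 3 passed adjusted over the list alone and 2 over all genes; adjusted p = 0.662 with an estimated correlation). Targets of p53 rose with 15 of 21 higher (median 0.36, adjusted p = 0.0386; 2 and 0; adjusted p = 0.498 with an estimated correlation), including Rps27l (1.56, SE 0.36) and Perp (1.39, SE 0.38). Activated fibroblast genes fell, with 12 of 16 lower (median -0.42, adjusted p = 0.0386; 0 and 0; adjusted p = 0.662 with an estimated correlation), including Fap, a surface protease gene of activated fibroblasts (-0.87, SE 0.23), while Comp gave 1.13 (SE 0.52). The interferon, collagen and matrix, and TGF-beta target lists each gave adjusted p = 0.768, and the collagen list had a median of 0.09 with a test below 0. EdgeR called 11 of 12299 genes (9 higher, 2 lower), 6 of them on chromosome X or Y. The count was 17 and 52 without WT replicate 1 and 2, 128 and 26 without Lmna-KO replicate 1 and 2. The p53 call was lost without each WT or Lmna-KO library (0.0696, 0.213, 0.134 and 0.126), and the glucocorticoid and activated fibroblast calls without WT replicate 2 (0.349 for both) or Lmna-KO replicate 1 (0.569 and 0.810).

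In fibroblasts, lists of activation, TGF-beta target and matrix genes rose with the vector relative to Lmna-KO. Activated fibroblast genes were higher in 15 of 16 (median 1.40, camera adjusted p = 4.52e-10; 4 passed adjusted over the list alone and 0 over all genes; adjusted p = 0.158 with an estimated correlation). Meox1, a transcription factor gene of fibroblast activation, was at 39.7 and 62.5 CPM against 14.7 and 18.5 (1.62, SE 0.35, adjusted p = 0.245 by edgeR), and Tnc, for the matrix protein tenascin C, at 91.2 and 219 against 4.91 and 35.5 (2.84, SE 0.66, adjusted p = 0.406). TGF-beta targets were higher in 14 of 16 (median 0.61, camera adjusted p = 4.04e-06; 4 and 0; adjusted p = 0.158 with an estimated correlation), with Ccn2 at 123 and 184 CPM against 55.3 and 52.5 (1.55, SE 0.27) and Thbs1 at 1.65 (SE 0.41). Collagen and matrix genes were higher in 21 of 26 (median 0.57, adjusted p = 6.55e-06; 5 and 0; adjusted p = 0.276 with an estimated correlation), with Col8a1 at 1040 and 1173 CPM against 267 and 374 (1.82, SE 0.31) and Col1a2 at 0.93 (SE 0.25). The collagen call was lost without Lmna-KO replicate 1 (0.0549). In the same comparison, the 10 cardiomyocyte markers had a median of 0.48 and 8 smooth muscle and pericyte markers a median of 0.44, close to the medians of the collagen and TGF-beta lists. The p53, interferon and glucocorticoid lists gave adjusted p from 0.0508 to 0.633. EdgeR called 1 of 12299 genes, BC018473, which was over 4 times higher in cardiomyocytes than in fibroblasts, and 804 had an unadjusted p under 0.05, where chance gives 615. The count was 14 and 18 without WT replicate 1 and 2, 12 and 51 without Lmna-KO replicate 1 and 2, and 2 without Lmna-KO+AAV replicate 1. The class held 449 and 520 nuclei in Lmna-KO and 864 and 617 with the vector.

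In endothelial cells of Lmna-KO mice, Igfbp3, which encodes a binding protein of insulin-like growth factors, rose to 119 and 136 CPM from 45.5 and 29.2 in WT (log2 change 1.70, SE 0.26, adjusted p = 0.0492 by edgeR, n = 2 per group). The cell adhesion genes Pcdh9 (-2.14, SE 0.20, adjusted p = 0.00181), Lsamp (-2.41, SE 0.27, adjusted p = 0.00593) and Negr1 (-2.64, SE 0.31, adjusted p = 0.00882) fell. Pcdh9 and Negr1 are also among the 10 top genes of fibroblast cluster 12. Fibroblasts made up 18.3% and 20.5% of WT nuclei against 8.47% and 11.3% of Lmna-KO nuclei. Whether free fibroblast RNA in the droplets contributed to these falls was not tested. EdgeR called 16 of 12797 genes (6 higher, 10 lower), of which 6 lie on chromosome X or Y. Without Lmna-KO replicate 1 the count was 182, without Lmna-KO replicate 2 it was 38, and without Lmna-KO+AAV replicate 1 or 2 it was 10 and 9. Igfbp3 was not called without WT replicate 2 (1.38, adjusted p = 0.130), Lmna-KO replicate 2 (0.0628) or Lmna-KO+AAV replicate 1 (0.194) or 2 (0.218), with only the 4 libraries compared (0.271), thinned sums (0.0702) or Leiden resolution 0.5 (0.0703), or without genes of chromosomes X and Y (1.70, adjusted p = 0.0795), nor Negr1 without WT replicate 2 (0.0572) or Lmna-KO+AAV replicate 2 (0.0529). With the 4 libraries, Negr1 (0.0697) and Lsamp (0.0555) were not called. None of the 5 lists was called (p53 targets, glucocorticoid-responsive genes, interferon response, endothelial activation, angiogenesis and tip cell genes), with camera adjusted p from 0.0878 to 0.886. Interferon genes were lower in 14 of 17 (median -0.37). The glucocorticoid list had a median of -0.01 with a mean and test above 0, endothelial activation a mean of 0.20 with a median and test below 0, and the angiogenesis list a median of 0.06 with a test below 0.

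With the vector, endothelial Nrg1, for the growth factor neuregulin 1, rose to 148 and 136 CPM from 42.8 and 44.8 in Lmna-KO (log2 change 1.80, SE 0.22, adjusted p = 0.0392 by edgeR). Nrg1 also leads the top genes of the endocardial cluster, and endocardial nuclei or RNA in the endothelial class were not tested for. Endocardial nuclei made up 6.53% and 9.21% in Lmna-KO and 3.66% and 5.06% with the vector. Lars2, for a mitochondrial leucyl-tRNA synthetase, rose to 946 and 947 CPM from 359 and 350 (1.52, SE 0.20, adjusted p = 0.0461), and Pid1 to 75.5 and 88.9 from 27.3 and 30.7 (1.60, SE 0.23, adjusted p = 0.0461). BC018473 rose to 577 and 557 CPM from 0 and 3.20 (8.55, SE 0.50, adjusted p = 0.000208), and 57.2% and 54.8% of endothelial nuclei with the vector held a UMI of it, against 57.8% and 58.1% of cardiomyocytes. These shares were not thinned and are not like values. Median depth was 1478 and 1440 UMIs in these endothelial nuclei against 3558 and 2825 in cardiomyocytes. Free RNA in the droplets was not tested as a source of BC018473. Endothelial nuclei were spread differently over their clusters: cluster 5, with a median of 1159 UMIs and 3.31% mitochondrial UMIs, held 60.1% and 74.4% of them with the vector against 19.2% and 32.4% in Lmna-KO, and cluster 4, with a median of 1837 UMIs and 1.80%, held 24.1% and 8.69% against 52.6% and 51.6%. EdgeR called 10 of 12797 genes, all higher, and 711 had an unadjusted p under 0.05, where chance gives 640. Nrg1, Pid1 and Lars2 were not called without Lmna-KO replicate 1 (0.218, 0.285 and 0.260), Lmna-KO+AAV replicate 1 (0.432 for each) or Lmna-KO+AAV replicate 2 (0.293, 0.549 and 0.465). Lars2 was also lost without Lmna-KO replicate 2 (0.0550) and Pid1 without WT replicate 1 (0.0581) or 2 (0.0522). Both were lost with only the 4 libraries (0.0847 and 0.106) and thinned sums (0.0529 and 0.0658), and Pid1 without doublet removal (0.0534) and at Leiden resolution 0.5 (0.0624). The count was 2 and 47 without Lmna-KO replicate 1 and 2, and 1 without either Lmna-KO+AAV library. The interferon response rose, with 14 of 17 members higher (median 0.31, camera adjusted p = 0.00161; 1 passed adjusted over the list alone and 0 over all genes; adjusted p = 0.643 with an estimated correlation), including Ifi44 at 17.9 and 11.1 CPM against 1.86 and 5.12 (2.15, SE 0.54, adjusted p = 0.484 by edgeR). That call was lost without Lmna-KO replicate 1 (0.865). The other 4 lists gave adjusted p from 0.217 to 0.872, and the angiogenesis list had a median of -0.09 with a test above 0.

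In macrophages, the gene of the inflammatory cytokine interleukin 1 beta, Il1b, rose in Lmna-KO to 70.6 and 126 CPM from 1.30 and 6.32 in WT (log2 change 4.74, SE 0.61, adjusted p = 0.0385 by edgeR, n = 2 per group), and stood at 11.6 and 18.5 CPM with the vector (-2.73 against Lmna-KO, SE 0.52, adjusted p = 0.582). Genes of recruited and inflammatory macrophages rose, with 17 of 18 higher (median 0.94, camera adjusted p = 0.00894; 1 passed adjusted over the list alone and 1 over all genes; adjusted p = 0.841 with an estimated correlation). Ccr2, the receptor of recruited monocytes, was at 35.3 and 231 CPM against 14.3 and 40.6 (2.35, SE 0.71, adjusted p = 0.418). Resident macrophage genes fell, with 10 of 12 lower (median -0.37, adjusted p = 0.0191; 0 and 0; adjusted p = 0.841 with an estimated correlation), including Cbr2 (-1.29, SE 0.44) and Cd163 (-0.85, SE 0.33). The p53, glucocorticoid and interferon lists gave adjusted p from 0.177 to 0.899; the glucocorticoid list had a median of -0.27 with a mean and test above 0, and the interferon list a median of 0.18 with a test below 0. EdgeR called 7 of 10833 genes (5 higher, 2 lower), and the 6 other than Il1b lie on chromosome X or Y. Lmna-KO replicate 1 held 78 macrophages. Il1b was not called without WT replicate 1 (3.92, adjusted p = 0.127), Lmna-KO replicate 1 (0.0813) or 2 (0.370), or Lmna-KO+AAV replicate 1 (0.0972) or 2 (0.0879), with only the 4 libraries compared (0.203), with thinned sums (0.0553), or without genes of chromosomes X and Y (4.74, adjusted p = 0.265), and the count was 15 without WT replicate 2 and 4 without Lmna-KO replicate 1, Lmna-KO+AAV replicate 1 or replicate 2. The recruited list was lost without WT replicate 1 (0.161) and turned to the lower side without Lmna-KO replicate 2 (0.732), and the resident list was lost without WT replicate 2 (0.339) or Lmna-KO replicate 1 (0.987) and without doublet removal (0.113).

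Between Lmna-KO+AAV and Lmna-KO macrophages, edgeR called 0 of 10833 genes, with 397 at an unadjusted p under 0.05, fewer than the 542 that chance gives, and 8 called by DESeq2. Interferon genes were higher in 11 of 12 (median 0.36, camera adjusted p = 0.00248), recruited macrophage genes in 11 of 18 (median 0.70, adjusted p = 0.0117) and p53 targets in 9 of 16 (median 0.35, adjusted p = 0.0247), while resident macrophage genes were lower in 10 of 12 (median -0.74, adjusted p = 0.0276). All 4 gave adjusted p = 0.516 with an estimated correlation. Adjusted over the list alone, 2 recruited genes (1 higher, 1 lower) and 1 p53 target passed, and 0 in the other 2 lists. Plk2, a p53 target, was at 70.6 and 63.1 CPM against 22.1 and 15.3 (1.92, SE 0.41, adjusted p = 0.686 by edgeR), and Cd163 at 171 and 221 against 419 and 359 (-0.98, SE 0.34). The glucocorticoid list was not called (adjusted p = 0.795; median -0.06, test below 0, mean 0.00). Without Lmna-KO replicate 1 the interferon list turned to the lower side (0.379) and the p53 (0.379) and recruited (0.852) lists were lost. Without Lmna-KO+AAV replicate 1 the interferon (0.0764), p53 (0.0797) and resident (0.105) lists were lost, and without replicate 2 the p53 (0.0830) and recruited (0.175) lists. The resident list was also lost without Lmna-KO replicate 2 (0.731), and the p53 list without WT replicate 1 (0.0893) or 2 (0.0768). Without doublet removal the recruited (0.322) and p53 (0.0978) lists were not called.

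Shares of nuclei per class were compared last, with exact Clopper-Pearson intervals that cover counting error. Cardiomyocytes made up 29.5% (28.5 to 30.6) and 30.6% (29.8 to 31.4) of WT nuclei, 52.2% (50.9 to 53.6) and 43.3% (41.9 to 44.7) of Lmna-KO nuclei and 57.6% (56.6 to 58.5) and 47.7% (46.6 to 48.8) of Lmna-KO+AAV nuclei. Fibroblasts made up 18.3% and 20.5% in WT, 8.47% and 11.3% in Lmna-KO and 8.49% and 7.80% in Lmna-KO+AAV. EdgeR on the numbers of nuclei called 0 of 14 classes in any of the 3 comparisons. Fibroblasts gave a log2 change of -0.97 (SE 0.35, unadjusted p = 0.0322, adjusted p = 0.225 by edgeR) and pericytes -1.04 (SE 0.35, unadjusted p = 0.0264, adjusted p = 0.225 by edgeR) in Lmna-KO against WT. For cardiomyocytes the changes were 0.67 (adjusted p = 0.425 by edgeR), 0.14 with the vector over Lmna-KO (0.853) and 0.81 with the vector over WT (0.215). With the stricter filter on nuclei, 4 classes were called between Lmna-KO+AAV and WT. Nuclei isolation, the UMI minimum and the uneven depth of the libraries can set such shares.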

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

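The tests of explanations in this part were chosen only after the values had been seen. Pericytes and endocardial cells enter the comparison of class shares but no comparison of gene levels in the report. Of their gene levels, only Lmna and BC018473 were looked at, which were already known to be higher with the vector in other classes. Each library with the vector was set against the highest of the 4 libraries without it. All 8 values looked at lay above it. Pericyte Lmna was at 202 and 205 CPM in the Lmna-KO+AAV libraries, where the highest library without the vector had 64.1 CPM, and pericyte BC018473 was at 999 and 561 CPM against at most 1.84. Endocardial Lmna was at 92.0 and 106 CPM against at most 64.6, and endocardial BC018473 at 193 and 244 CPM against at most 1.57. The difference was not tested in these classes.

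Lmna tags outside cardiomyocytes in the vector libraries may come from free cardiomyocyte RNA in the droplets or from vector RNA made in the other classes. If free RNA were the source, the rise of Lmna over Lmna-KO should follow the cardiomyocyte marker RNA of each class. Without nuclei of 10 or more Lmna UMIs, the rise per 1000 CPM of markers over 5 classes was 5.24 to 7.88 in Lmna-KO+AAV replicate 1. In replicate 2 it was 5.42 to 11.9. Cardiomyocytes, with all nuclei kept, gave 5.37 and 11.3, within these ranges. The highest ratio of the rise to the markers over the 5 classes was 2.20 times the lowest in replicate 2 and 1.504 times in replicate 1. This lies between the limits set for a yes or a no, so the test of the other classes cannot tell. For RNA made in these nuclei, 35 of 6838 nuclei held 5 or more Lmna UMIs where Poisson counting gives 0.285. Without the vector 16 of 16102 did, where it gives 0.0526, so an excess over Poisson counting at 5 or more UMIs was also seen without it. Nuclei of 10 or more Lmna UMIs, however, were found in these classes only with the vector. In replicates 1 and 2 they were 0 and 1 fibroblasts, 3 and 2 endothelial, 1 and 2 endocardial, 1 and 1 pericyte and 2 and 0 macrophage nuclei. The 35 nuclei held 1.31 times the cardiomyocyte marker share of the rest of their class, so a cardiomyocyte joined to them in a droplet could not be ruled out, and this test cannot tell either.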

How the results depend on the processing

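Settings without genes of chromosomes X and Y, without clusters 14 and 17, and with the Lmna-KO libraries split between comparisons were chosen only after the data had been seen, as were all comparisons of Lmna-KO+AAV with WT outside cardiomyocytes, their lists included. Of 4127 comparisons of 257 named gene results with another setting, 3638 kept direction and side of the threshold. A call was lost in 230 and gained in 254, and 5 turned or came to 0. Most of these results were not called and had no call to lose. The 100 called ones kept their call in 1353 of 1583 comparisons and lost it in 230. The 45 called lists kept theirs in 416 of 582, lost them in 163 and turned in 3. Unless a reason is given, the cause was not tested.

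For Lmna-KO against WT, counts of genes called in cardiomyocytes, fibroblasts, endothelial cells and macrophages were 328, 95, 148 and 23 with DESeq2 and 700, 397, 533 and 173 without a filter on low counts. Without genes of chromosomes X and Y they were 0, 4, 6 and 0, where 0, 5, 10 and 1 of the genes called with them lie elsewhere, so calls on other chromosomes were lost too. The stricter nuclei filter gave 16 in cardiomyocytes. Fibroblasts gave 22 with the replicate block and 17 with thinned sums; endothelial cells gave 7 with only the 4 libraries compared; macrophages gave 4 with the 4 libraries, 4 with thinned sums and 15 without doublet removal.

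For Lmna-KO+AAV against Lmna-KO, the counts in the same order were 191, 36, 25 and 8 with DESeq2 and 646, 193, 172 and 69 without a filter. Cardiomyocytes gave 25 with RLE size factors, 1 with 4 libraries, 1 without doublet removal (where the BC018473-rich cluster stayed unnamed), 3 with the stricter filter and 1 without clusters 14 and 17. Fibroblasts gave 9 with 4 libraries, 10 with the block, 3 with thinned sums and 0 without genes over 4 times higher in cardiomyocytes, by construction. Endothelial cells gave 4, 6 and 3 in the first 3 of these and 5 at Leiden resolution 0.5, and macrophages 1 without doublet removal. For Lmna-KO+AAV against WT, cardiomyocytes gave 843 with DESeq2, 1521 without a filter, 533 with 4 libraries, 292 with the block, 92 with thinned sums, 34 without doublet removal and 19 without clusters 14 and 17. Fibroblasts, endothelial cells and macrophages gave 330, 426 and 77 with DESeq2, 692, 943 and 371 without a filter, 432, 544 and 19 with 4 libraries and 331, 384 and 86 with the block, fibroblasts 129 with thinned sums, and macrophages 2 without genes of chromosomes X and Y.

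Cardiomyocyte Lmna over Lmna-KO was 4.07 with 4 libraries, 3.72 without doublet removal, 3.88 with the stricter filter and 2.72 without clusters 14 and 17, each no longer called, and over WT 2.07 without those clusters. Lmna gained a call in fibroblasts over Lmna-KO with DESeq2 (2.35), no filter (2.35) and the block (2.29), and in macrophages with no filter (1.71, and 1.47 over WT) and the block (1.496 over WT). Unthinned shares of cardiomyocytes with Lmna were 19.7%, 11.4% and 41.9% in WT, Lmna-KO and Lmna-KO+AAV. With an estimated correlation 0 lists were called in any comparison, and fry called 0 and 1 (Lmna-KO against WT, cardiomyocytes and other classes), 1 and 0 (Lmna-KO+AAV against Lmna-KO) and 1 (against WT, cardiomyocytes), the integrated stress response in both cardiomyocyte comparisons with the vector. Against WT with the vector it also called p53 targets in fibroblasts (0.00554) and endothelial cells (0.00746), the smallest values it gave there. The overlap count was 27 with DESeq2, and 4 class shares were called against WT with the stricter filter, which left fibroblasts, endothelial cells and macrophages under 50 nuclei in a library, so their genes were not tested there.

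Leaving out 1 library at a time, with the lone library assumed to vary like the other groups, gave 5 to 24, 8 to 128, 9 to 182 and 4 to 15 genes (Lmna-KO against WT, classes as above), 3 to 71, 1 to 51, 1 to 47 and 0 to 0 (Lmna-KO+AAV against Lmna-KO), and 8 to 528 in cardiomyocytes against WT. Lmna ranged from -0.86 to -0.40, -0.76 to -0.13, -0.89 to -0.64 and -0.47 to 0.15 in Lmna-KO against WT, 3.46 to 4.50, 1.56 to 2.87, 2.27 to 2.57 and 1.51 to 1.90 in Lmna-KO+AAV against Lmna-KO, and 2.80 to 3.86, 1.18 to 2.47, 1.51 to 1.81 and 1.19 to 1.81 in Lmna-KO+AAV against WT. Lists called ranged from 0 to 5 and 1 to 10 (cardiomyocytes and other classes, Lmna-KO against WT), 6 to 8 and 4 to 10 (Lmna-KO+AAV against Lmna-KO) and 6 to 9 (cardiomyocytes, against WT), the overlap from 0 to 3, and class shares called from 0 to 0.

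Of the named genes, those that turned or came to 0 were Trib3 in cardiomyocytes over WT without clusters 14 and 17 (-0.0555), Dusp1 in endothelial cells over WT without Lmna-KO+AAV replicate 2 (-0.00347, range to 0.72), and in macrophages Gpnmb (0, range to 6.68), Timd4 (0.0278, range from -4.42) and Lyve1 (0.0558, range from -2.60) without Lmna-KO replicate 2. The Lmna levels, counted apart, turned in macrophages without WT replicate 2 (0.15). The lists that turned were fatty acid oxidation in cardiomyocytes (adjusted p = 0.891 without Lmna-KO+AAV replicate 1, range from 1.09e-11), recruited macrophage genes (0.732 without Lmna-KO replicate 2, range from 7.71e-08) and the macrophage interferon response (0.379 without Lmna-KO replicate 1, range from 1.37e-05). Replicates with the same number did not pair: over 5000 genes their residuals correlated at r = 0.192, -0.01 and -0.03, so the block is given only here. With it the sarcomere list in Lmna-KO (0.0728) and endothelial Lars2 (0.0655) and Pid1 (0.0585) with the vector lost their calls, as did glucocorticoid-responsive genes in endothelial cells over WT (0.0583). The lowest sums were 814185 UMIs in fibroblasts and 226597 in macrophages, both of Lmna-KO replicate 1. In simulated counts 56% of 4-fold changes were recovered in macrophages and 72% in fibroblasts, against 60% in the deeper cardiomyocytes.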

Other observations

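The comparisons of Lmna-KO+AAV with WT outside cardiomyocytes, and the tests of explanations below, were chosen only after the data had been seen. In fibroblasts, Ccn2, Thbs1 and Meox1 were higher with the vector than in WT. Ccn2, a TGF-beta target, was at 123 and 184 CPM against 34.8 and 30.4 (log2 change 2.20, SE 0.26, adjusted p = 0.00498 by edgeR, n = 2 per group), Thbs1 at 116 and 180 against 35.2 and 15.3 (2.52, SE 0.39, adjusted p = 0.0218), and Meox1 at 39.7 and 62.5 against 13.6 and 17.7 (1.66, SE 0.30, adjusted p = 0.0293). Mt1 stayed above WT (2.51, SE 0.28, adjusted p = 0.00411), while Vit, for a matrix protein, fell to 15.4 and 25.01 from 114 and 71.0 CPM (-2.24, SE 0.34, adjusted p = 0.0210). Vit is among the 10 top genes of fibroblast clusters 12 and 21. Cluster 12 held 9.95% and 4.70% of fibroblasts with the vector against 13.5% and 22.9% in WT. Cluster 21 held 7.99% and 12.2% against 7.69% and 1.91%. Whether this mix of clusters changed the level of Vit was not tested. All 6 lists rose: collagens and matrix with 22 of 26 higher (camera adjusted p = 7.60e-05), TGF-beta targets with 14 of 16 (7.60e-05), activated fibroblast genes with 14 of 16 (0.000107), p53 targets with 15 of 21 (0.000397), glucocorticoid-responsive genes with 6 of 11 (0.0148) and interferon response with 10 of 11 (0.0205), and with an estimated correlation the smallest was adjusted p = 0.168. The glucocorticoid call was lost without WT replicate 2 (0.368) or Lmna-KO+AAV replicate 2 (0.102), and the interferon call without WT replicate 2 (0.0615) or Lmna-KO+AAV replicate 1 (0.316). EdgeR called 201 of 12299 genes (172 higher, 29 lower; 13 on chromosome X or Y), but 33 without WT replicate 1, 455 and 468 without Lmna-KO replicate 1 and 2, and 14 and 7 without Lmna-KO+AAV replicate 1 and 2. Without Lmna-KO+AAV replicate 2, Ccn2 (1.89, adjusted p = 0.0973), Mt1 (2.25, 0.0804), Thbs1 (0.235), Meox1 (0.327) and Vit (0.177) were not called. Without Lmna-KO+AAV replicate 1, Thbs1 (0.123), Meox1 (0.133) and Vit (0.217) were not called, and without WT replicate 1, Meox1 (0.140).

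In endothelial cells with the vector, the cell adhesion gene Lsamp (-2.20, SE 0.25, adjusted p = 0.00544 by edgeR) fell relative to WT, and the metal-binding gene Mt1 rose to 44.6 and 64.7 from 17.9 and 12.1 CPM (1.90, SE 0.30, adjusted p = 0.0178). EdgeR called 219 of 12797 genes (195 higher, 24 lower; 15 on chromosome X or Y), 18 without WT replicate 1, 580 and 586 without Lmna-KO replicate 1 and 2, and 9 without either Lmna-KO+AAV library. Cluster 5, of fewer UMIs and more mitochondrial UMIs, held 60.1% and 74.4% of endothelial nuclei with the vector against 9.07% and 25.6% in WT, and cluster 4 held 24.1% and 8.69% against 67.7% and 42.8%. Without Lmna-KO+AAV replicate 1 or 2, Lsamp (0.157 and 0.126) and Mt1 (0.157 and 0.197) were not called, nor Mt1 without WT replicate 1 (0.0638) or 2 (0.0580). Of the 5 lists, glucocorticoid-responsive genes rose with 8 of 11 higher (camera adjusted p = 0.0466; adjusted p = 0.863 with an estimated correlation), a call lost without WT replicate 2 (0.438), Lmna-KO replicate 1 (0.0813) or 2 (0.0810), or Lmna-KO+AAV replicate 2 (0.458), and the other 4 (p53 targets, interferon response, endothelial activation, angiogenesis) gave 0.0540 to 0.946. The interferon list had a median of -0.06 with a mean and test above 0, and the angiogenesis list a mean of 0.12 with a median and test below 0. Macrophages with the vector showed more RNA of recruited macrophage genes than WT, with 16 of 18 higher (adjusted p = 4.09e-08; 11 passed adjusted over the list alone and 1 over all genes), and less of resident genes, with 11 of 12 lower (2.54e-05; 5 and 0). Gpnmb, a gene of lipid-laden macrophages, had 0 counts in both WT libraries and Lmna-KO replicate 1, 13.4 CPM in Lmna-KO replicate 2 and 45.1 and 110 CPM with the vector (adjusted p = 0.0488 by edgeR). That call was lost without WT replicate 1 (0.115), Lmna-KO+AAV replicate 1 (0.0695) or replicate 2 (0.277), without genes of chromosomes X and Y (0.0960), with RLE size factors (0.0517), with thinned sums (0.137) and at Leiden resolution 0.5 (0.0548). Targets of p53 were higher in 13 of 16 (0.00160) and interferon genes in 12 of 12 (0.00175; 0.0535 without doublet removal), while glucocorticoid-responsive genes gave 0.104 (median -0.02, mean and test above 0). With an estimated correlation the recruited, resident and p53 lists gave adjusted p = 0.247 and the interferon list 0.435. EdgeR called 12 of 10833 genes (10 higher, 2 lower), of which 6 lie on chromosome X or Y, and 2 without genes of those chromosomes, with 7 and 31 without WT replicate 1 and 2, 21 and 23 without Lmna-KO replicate 1 and 2, and 5 without either Lmna-KO+AAV library.

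Cardiomyocyte nuclei with 10 or more Lmna UMIs were set beside those with 1 or 0 in the Lmna-KO+AAV libraries, as values without a test. In replicates 1 and 2, the early response gene Btg2 was 15.1 and 5.20 times higher in the Lmna-rich nuclei, the heat shock gene Hspb1 13.7 and 5.06 times, Nppb 7.96 and 3.96 times, Dancr 8.22 and 4.26 times, Gm9750 32.3 and 25.9 times, Kazn 10.4 and 1.87 times and Txnip 3.71 and 12.9 times. The calcium channel genes Cacna1c and Ryr2 were at 0.218 and 0.375 and at 0.249 and 0.381 of the level in the other nuclei, and Rnf207 at 0.197 and 0.272. These 138 and 210 nuclei were compared with 4918 and 2809. This comparison and its genes were not part of the plan set beforehand, and Gm9750 lies outside the naming rule. Of the Lmna-rich nuclei, 31.2% and 37.6% held no BC018473 UMI. Their mitochondrial share and depth were not set beside those of the other nuclei, so damage was not told apart.

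Most cardiomyocyte UMIs of BC018473 lay in few nuclei. Those with 10 or more of its UMIs made up 2.90% and 4.26% of cardiomyocytes with the vector (170 of 5856 and 161 of 3776) and held 83.9% and 91.5% of these UMIs. Without thinning to equal depth, 57.8% and 58.1% of cardiomyocytes, and 57.2% and 54.8% of endothelial nuclei, held any. In the other libraries 0 cardiomyocytes with 10 or more were found, with upper limits of 0.137% and 0.0767% in WT and 0.108% and 0.151% in Lmna-KO. A tag on all vector RNA of Lmna could explain this. Lmna UMIs per BC018473 UMI were 41.7 and 169 times higher in the other cardiomyocytes than in these nuclei (1.54 and 2.91 against 0.0368 and 0.0172). The nuclei were split by their BC018473 UMIs, which by itself sets these ratios apart, so they cannot decide. Of nuclei with 10 or more Lmna UMIs, picked by Lmna alone, 31.2% and 37.6% held no BC018473. Poisson counting at the ratio of the other cardiomyocytes gives 0.0229% and 0.656%, which argues against a tag on all vector RNA of Lmna. A tag on part of that RNA stays open. Lmna was at 2360 and 1334 CPM in nuclei with 10 or more BC018473 UMIs against 340 and 770 CPM in the other cardiomyocytes. Of these nuclei 31.2% and 39.1% held no Lmna UMI, where Poisson counting at their mean ratio of the 2 tags gives 19.3% and 23.0%, between the limits set for a yes or a no, so this cannot tell. Doublets could too, but the median UMI number of these nuclei was 0.535 and 0.640 times that of other cardiomyocytes, which argues against them. Their median mitochondrial share was 1.78 and 1.61 times as high, which fits damaged nuclei. As they also held fewer UMIs and shares were not compared at equal depth, damage was not told apart from low depth. Macrophages held it without the vector, at 85.2 and 24.4 CPM in WT and 97.1 and 24.8 in Lmna-KO, against 554 and 401 with the vector. Whether counting used strand is not given, and no biological explanation was tested.

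The higher activated fibroblast genes with the vector may also have a technical source. Smooth muscle or pericyte nuclei in the class could raise them, but 8 markers of those types had a median log2 change of 0.44 against 1.40 for the list. Free cardiomyocyte RNA could as well, but 10 cardiomyocyte markers had a median of 0.48. In the largest fibroblast cluster alone, the list's median log2 ratio was 1.18 against 1.39 over all fibroblasts, which argues against another mix of clusters. That the rise goes with the vector group remains a hypothesis, since each group has 2 mice and the list gave adjusted p = 0.158 with an estimated correlation.

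An unnamed cluster of 66 nuclei was led by the neuronal genes Snhg11, Tenm2 and Nrg3, and 65 of its nuclei came from WT replicate 1.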
